A study of Homo sapiens with 42 samples.

How the data were processed

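RNA was measured by sequencing in 42 libraries of human umbilical vein endothelial cells, 2 for each of 21 groups of flow and time. The libraries were made from polyA-selected RNA with a stranded kit and sequenced as 50-bp single-end reads, per the labels. The labels call the 2 libraries of a group biological replicates and name them set A and set B. Whether a set stands for a batch of cells, a run or a day is not given in the sources used here.

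The deposited table holds estimated counts (expected counts) per RefSeq transcript model on hg19, per the file headers and the values. The values are fractional per transcript: of those above 5, 31.8% lay within 0.005 of a whole number, against 71.6% after summing the transcripts of a gene. The aligner and the program that split shared reads are not given in the sources used here. Values of the 36004 transcript models were summed per gene symbol (22300 symbols), rounded to whole counts and used as counts. XIST, TSIX and Y-linked genes were left out of every table, which left 22198 genes. Library totals ran from 23.6 to 52.7 M counts with a median of 31.9 M, and 12993 to 13772 genes per library had at least 10 counts.

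Genes with too few counts were removed with filterByExpr (minimum count 10, minimum total 15), which left 14302 genes. Counts were scaled by trimmed means of M values (factors 0.970 to 1.05) and fitted with the quasi-likelihood model of edgeR 4.0.16 in R 4.3.3. A single model with a mean for each of the 21 groups was used for every comparison, so that the spread came from all 42 libraries (21 residual degrees of freedom). The model held no term for the set and treated the libraries of a set as independent. Where times are averaged, n therefore counts libraries over several times in 2 sets and not independent replicates. The common biological coefficient of variation was 13.6%. Adjusted p-values are Benjamini-Hochberg values over the 14302 genes of a comparison, and a gene was called when its adjusted p was below 0.05. Fold changes are on the log2 scale, PS minus OS, flow minus ST, or late minus early. Their standard error (SE) was the absolute fold change divided by the square root of the F statistic of the test. It rests on the spread over all 42 libraries, and the n beside it gives the libraries compared. Early stands for the mean of 1 to 4 h and late for the mean of 12 to 24 h, each 4 times and 8 libraries per flow. Simulated counts, drawn independently at the trended spread of these libraries, were used to test the fit. They held no difference between sets and no trend with GC content or length, so that the rates may not carry over to the real libraries. The fit recovered 88% of genes changed 1.5-fold and 98% of genes changed 2-fold in the mean over 10 times, with 12 false calls among 198. At 24 h alone it recovered 26% and 70%, and for PS against ST 20% and 67%.

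Gene lists were written before the data were examined, as were the comparisons, the windows, the thresholds and the rule for named genes. The 28 lists were KLF2/KLF4-associated flow genes, NRF2 antioxidant genes, NF-kB and leukocyte adhesion genes, immediate early genes, cholesterol synthesis and uptake, G2/M cell cycle, DNA replication and G1/S, YAP/TAZ targets, BMP/SMAD targets, Notch and arterial genes, pan-endothelial identity, vasoactive genes, haemostasis genes, angiogenic and tip cell genes, unfolded protein and amino acid stress response, heat shock genes, hypoxia and glycolysis, extracellular matrix, mesenchymal and contractile genes, interferon response, circadian clock genes, flow sensors, and markers of fibroblasts, smooth muscle and pericytes, leukocytes, red cells, epithelium and lymphatic endothelium. Of 443 list entries, 405 were measured, and 27 lists had a measured member. Some genes, such as NOS3, TEK and KDR, were in more than 1 list, so that the list tests are not independent. Shared with other lists were 6 pan-endothelial identity genes, 5 flow sensors and 5 KLF2/KLF4-associated flow genes, among others. Each list was tested against all other genes with camera (limma 3.58.1) at its preset inter-gene correlation of 0.01 and again with an estimated correlation. List p-values were adjusted by Benjamini-Hochberg over the 27 lists of a comparison. Counts of called members are given over all genes tested and, in parentheses, adjusted over the list alone.

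Genes were named by rule. For the mean over 10 times these were the 10 with the largest rise and the 10 with the largest fall among called genes with a mean log2 CPM (counts scaled to the library total) of at least 2, the same sign in both sets and the same sign at 8 or more times. In the other comparisons these were 5 in each direction by the same rule without the condition on times. Up to 4 list members with the smallest p and 12 genes followed over time were added. Uncharacterised loci were passed over.

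The alternatives tried were median-of-ratios (RLE) scaling, no count filter, a filter at a mean log2 CPM of 2, the Wald test of DESeq2 1.42.0, a replicate block (the set as a term), the compared groups alone, each set alone, narrower windows (1 to 3 h and 16 to 24 h), and each library left out in turn. Chosen after the data were seen were a fit without the 20 h time point, a fit for the late minus early difference within each set, and a correction for each library's smooth trend with transcript GC content and length. The last took length from the deposited table and GC content from reference transcript sequences matched by RefSeq identifier, then by symbol. GC content was found for 14043 of the 14302 genes, and the others were given the median. Other groupings were 100 splits of the libraries per comparison, the real grouping among them. No check for mixed-up samples was run. Figures were drawn with matplotlib 3.10.9.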

Results

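Messenger RNA was measured in human umbilical vein endothelial cells, primary cells of the vein lining, kept under flow for 1 to 24 h. Shear stress in dyn/cm2 was 12 ± 5 in pulsatile flow (PS), 0.5 ± 5 in oscillatory flow (OS) and 0.5 in the low laminar flow (ST). PS and OS were sampled hourly from 1 to 4 h, at 6 h and 9 h, and every 4 h from 12 to 24 h. Each of these groups had 2 libraries, 1 of set A and 1 of set B. ST was sampled at 1 h with 2 libraries. The total count was 32.8 ± 3.47 M in PS (SD, n = 20, range 27.0 to 39.3). It was 32.4 ± 6.18 M in OS (SD, n = 20, range 23.6 to 52.7), and 24.1 M and 33.9 M in the ST libraries. The 10 most abundant genes took 9.08 to 13.7% of the counts of a library. The first principal component of log2 CPM held 34.8% of the variance and the second 12.0%.

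**Figure D1:**
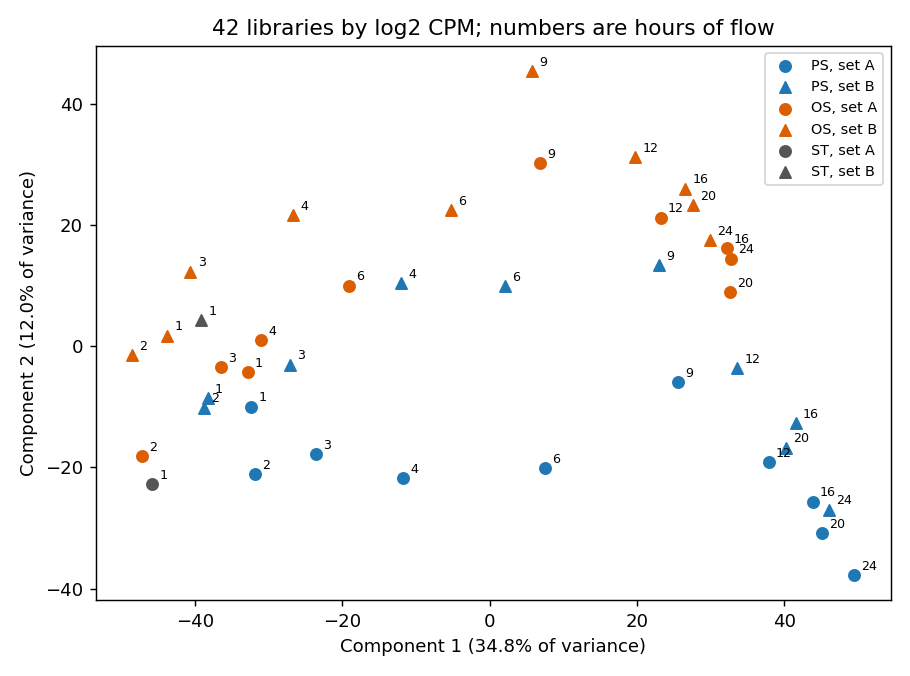
The first and second principal components of log2 CPM for the 42 libraries, which hold 34.8% and 12.0% of the variance. Each point is a library marked with its hours of flow, with colour for flow and shape for set.

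Which genes differ between pulsatile and oscillatory flow over the whole course was asked with the mean of the 10 differences at matched times. KLF2, a flow-responsive transcription factor of endothelium (chromosome 19, 16435651 to 16438339 in hg19), was higher in PS by 2.95 ± 0.13 on the log2 scale (SE, n = 20 libraries per flow, adjusted p = 4.1e-15), by 3.16 in set A and 2.79 in set B. KLF4, a related factor (chromosome 9, 110247133 to 110252047), was higher by 2.70 ± 0.09. The other genes that rose most under the naming rule were CYP1B1, a cytochrome P450 (2.80 ± 0.19), NPR1, a natriuretic peptide receptor (2.46 ± 0.18), and CNR1, a cannabinoid receptor (2.45 ± 0.10). Next under that rule came ITGB4, an integrin (2.37 ± 0.09), the prostaglandin transporter SLCO2A1 (2.13 ± 0.10), CLIC3 (1.98 ± 0.10), PLVAP (1.87 ± 0.10) and MN1 (1.81 ± 0.10). CXCR4, a chemokine receptor (chromosome 2, 136871919 to 136875725), was lower in PS with a log2 difference of -2.29 ± 0.12, and ANGPT2, a ligand of the TEK receptor (chromosome 8, 6357175 to 6420784), with -1.69 ± 0.10. Lower too were F3, which encodes tissue factor (-1.56 ± 0.15), the BMP antagonist NOG (-1.31 ± 0.16), the apoptosis gene BCL2L11 (-1.26 ± 0.11) and the leukocyte adhesion gene SELE (-1.12 ± 0.27). Smaller falls were seen in PIM3 (-1.10 ± 0.09), RASSF2 (-1.10 ± 0.07), TNFSF15 (-1.06 ± 0.10) and FAM84B (-1.02 ± 0.08).

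Among genes followed over time, the nitric oxide synthase NOS3 (chromosome 7, 150688144 to 150711687) was higher in PS by 1.55 ± 0.07 and the anticoagulant receptor gene THBD by 1.26 ± 0.11. The chemokine gene CCL2 (-0.79 ± 0.12), the endothelin gene EDN1 (-0.54 ± 0.04) and CTGF (-0.26 ± 0.03) were lower. VCAM1 (-0.48 ± 0.23, adjusted p = 0.11), ICAM1 (0.19 ± 0.10, adjusted p = 0.14), HMOX1 (0.09 ± 0.08, adjusted p = 0.39) and HMGCS1 (0.01 ± 0.05, adjusted p = 0.93) did not pass the test. Of 18 KLF2/KLF4-associated flow genes, 16 were higher in PS and 0 lower (17 and 0 adjusted over the list alone), with a camera adjusted p of 6.5e-56 and 6.6e-06 with an estimated correlation. They included SLC9A3R2 (1.79 ± 0.08) and TEK (1.02 ± 0.05). Of 16 pan-endothelial identity genes, 8 were higher and 1 lower (8 and 1 adjusted over the list alone, camera adjusted p = 2.2e-05), and the adjusted p was 0.424 with an estimated correlation. SOX18, a transcription factor, rose by 1.63 ± 0.17, and the 1 lower gene was ERG, chosen after its value was seen (-0.12 ± 0.03). Of 16 vasoactive genes 8 were higher and 2 lower, EDN1 and ADM (8 and 2 adjusted over the list alone, camera adjusted p = 0.00972, adjusted p = 0.658 with an estimated correlation). Of 17 Notch and arterial genes 9 were higher, such as GJA5 (1.24 ± 0.13) and HEY1 (0.69 ± 0.09), and 1 lower, CXCR4 (9 and 1 adjusted over the list alone, camera adjusted p = 0.0318, adjusted p = 0.658 with an estimated correlation).

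Of 14 flow sensor genes 9 were higher in PS and 1 lower (9 and 2 adjusted over the list alone, camera adjusted p = 0.00972, adjusted p = 0.658 with an estimated correlation). The lower gene was the ion channel P2RX4, chosen after its value was seen (-0.45 ± 0.08). Of 14 mesenchymal and contractile genes 7 were lower and 1 higher, FSTL1 with 0.25 ± 0.02 (7 and 1 adjusted over the list alone, camera adjusted p = 0.0167, adjusted p = 0.483 with an estimated correlation). Of 17 angiogenic and tip cell genes 7 were higher and 7 lower (7 and 8 adjusted over the list alone, camera adjusted p = 0.0323 toward lower, adjusted p = 0.643 with an estimated correlation), and the list was not called with the replicate block (adjusted p = 0.0864). Of 20 genes of DNA replication and G1/S 5 were lower and 0 higher (3 and 0 adjusted over the list alone). The test of that list gave a camera adjusted p of 0.0240, and 0.854 with an estimated correlation. In the hypoxia and glycolysis list 12 of 18 genes were lower and 2 higher, NDRG1 (1.00 ± 0.05) and SLC2A3 (0.37 ± 0.03), with 12 and 3 adjusted over the list alone, and the list test gave an adjusted p of 0.129. Of 18 NRF2 antioxidant genes 2 were higher and 2 lower (2 and 1 adjusted over the list alone, camera adjusted p = 0.575). In all, 2414 genes were higher in PS and 2578 lower among 14302 by edgeR, and 166 and 52 of these differed at least 2-fold. The sign was the same in both sets for 4990 of the 4992. This and the like counts below are no separate support, since the genes were called from a fit of both sets. Set A alone called 3586 genes (1760 higher and 1826 lower) and set B alone 2843 (1602 and 1241). Which direction held more genes also turned with the stricter filter (2143 higher and 1931 lower) and without the 20 h time point (2078 and 2065). It turned without any 1 of 14 of the 40 libraries, OS set A of 2 or 12 h, OS set B of 1 h, PS set A of 1, 2, 6, 20 or 24 h and PS set B of 1, 2, 3, 6, 9 or 24 h. The counts were 2397 and 2274 without PS set A of 1 h and 2509 and 2183 without OS set A of 12 h, the smallest and largest excess of the 14.

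When the flows part was asked with the same difference at each of 10 times. KLF2 was higher in PS at all 10, by 2.47 ± 0.40 at 1 h, 4.30 ± 0.45 at 4 h and 2.32 ± 0.40 at 24 h (SE, n = 2 libraries per group). At 1 h the KLF2 level was 98.4 ± 3.86 CPM in PS, 17.8 ± 2.01 CPM in OS and 21.8 ± 9.41 CPM in ST (SD, n = 2). KLF4 was higher at all 10 times as well, by 1.70 ± 0.27 at 1 h, 3.23 ± 0.29 at 6 h and 2.83 ± 0.28 at 24 h. NOS3 passed the test from 3 h on (1.09 ± 0.21, adjusted p = 0.014) and reached 2.58 ± 0.22 at 9 h. THBD passed from 6 h on (1.69 ± 0.34), with 2.42 ± 0.35 at 9 h. ANGPT2 was lower from 4 h on (-1.21 ± 0.29), and its difference was -3.13 ± 0.34 at 24 h, when its level was 1.64 ± 0.393 CPM in PS and 14.4 ± 3.20 CPM in OS (SD, n = 2). EDN1 passed as lower at 2, 3, 9, 12, 16, 20 and 24 h, with -0.72 ± 0.11 at 2 h and -0.56 ± 0.11 at 24 h. Its mean level was lower in PS at the other times too, with 741 ± 31.9 CPM against 1056 ± 153 CPM in OS at 1 h (SD, n = 2). Calls of single genes between PS and OS at single times were not rechecked with libraries left out. HMGCS1, an enzyme of cholesterol synthesis, passed at 24 h alone (0.47 ± 0.15, adjusted p = 0.045), and CCL2, VCAM1, ICAM1, HMOX1 and CTGF passed at none of the 10 times. At 3 h the HMGCS1 level was lower in PS, 31.3 ± 0.686 CPM against 46.7 ± 1.46 CPM in OS (SD, n = 2), without passing. The p that passes after adjustment depends on the calls at a time, 31 at 3 h and 1226 at 24 h. A time without a call therefore does not show equal levels.

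At 1 h, 6 genes were higher in PS and 4 lower. The 4 lower genes were CD69 (-3.02), CXCR4 (-2.14), PDE4B (-1.68) and PIM1 (-1.28), named here after their values were seen. With a library left out, the 10 calls at 1 h became 2 without OS set A, 1 without PS set A, 29 without OS set B and 4 without PS set B. There were 37 with the replicate block, 31 with DESeq2 and 0 in a fit of the PS and OS libraries of 1 h alone. At 24 h, 743 genes were higher in PS and 483 lower, and 310 and 107 of these differed at least 2-fold. The 1226 calls at 24 h became 406 without OS set A, 495 without PS set A and 581 without PS set B. With the replicate block the balance at 24 h turned, to 1211 higher and 1269 lower. CD34, a surface glycoprotein of endothelium (chromosome 1, 208059883 to 208084683), had a difference of -0.89 ± 0.49 at 1 h (adjusted p = 0.999), 2.24 ± 0.52 at 9 h and 4.98 ± 0.60 at 24 h (adjusted p = 2.8e-06).

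**Figure D2:**
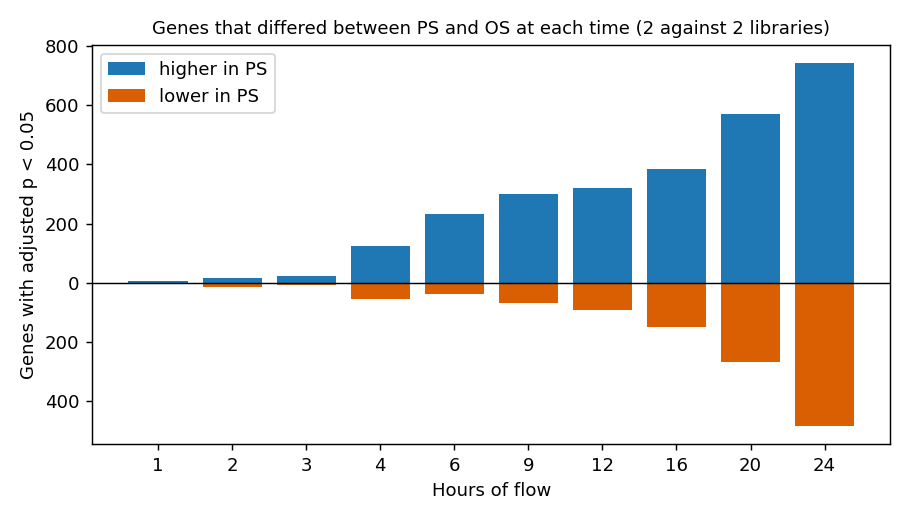
Number of genes called higher (up) and lower (down) in PS than in OS at each of the 10 times, 2 libraries per group. The bars run from 6 higher and 4 lower at 1 h to 743 higher and 483 lower at 24 h.

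**Figure D3:**
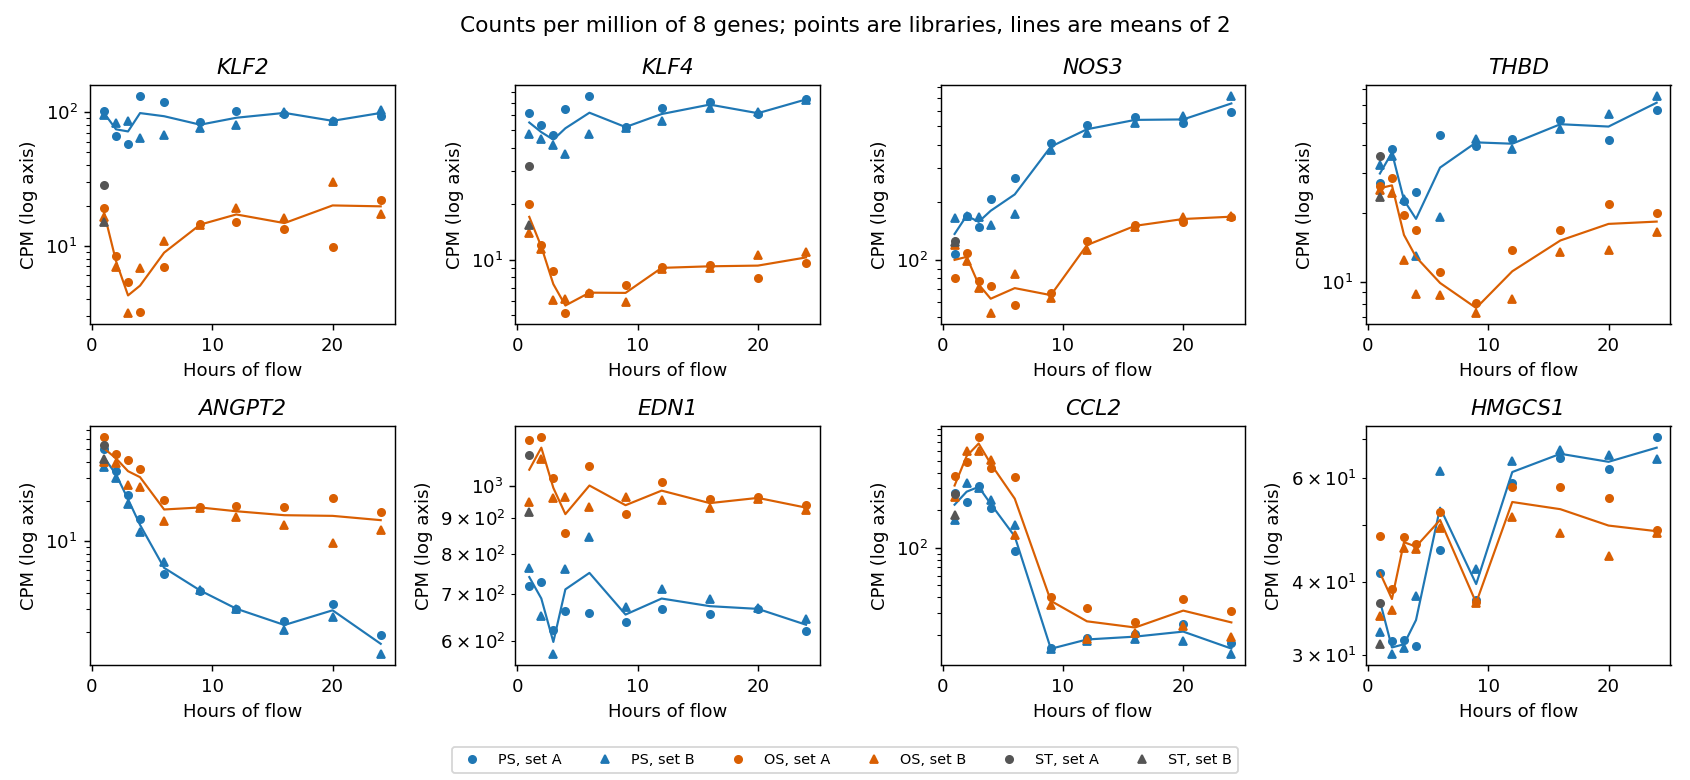
CPM (log axis) of KLF2, KLF4, NOS3, THBD, ANGPT2, EDN1, CCL2 and HMGCS1 against hours of flow. Points are libraries and lines are means of 2 libraries, and KLF2 stood at 98.4 CPM in PS and 19.7 CPM in OS at 24 h.

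Early differences were asked with the mean of 1 to 4 h. KLF2 was higher in PS by 3.53 ± 0.22 (SE, n = 8 libraries per flow, adjusted p = 3.0e-11), KLF4 by 2.38 ± 0.14, CYP1B1 by 1.90 ± 0.29, NPR1 by 1.70 ± 0.28 and PLVAP by 1.70 ± 0.16. CXCR4 (-2.04 ± 0.18), F3 (-1.45 ± 0.23), the kinase MAP3K8 (-1.36 ± 0.18), BCL2L11 (-1.30 ± 0.17) and the phosphodiesterase PDE4B (-1.12 ± 0.13) were lower. Of the genes followed over time, NOS3 was higher (0.94 ± 0.10), CCL2 (-0.92 ± 0.18), EDN1 (-0.58 ± 0.06) and HMGCS1 (-0.36 ± 0.07) were lower, and THBD did not pass the test (0.44 ± 0.16, adjusted p = 0.12). ANGPT2 was lower (-0.64 ± 0.14), a call lost in set B alone (-0.50, adjusted p = 0.10) and with the mean of 1 to 3 h (-0.45, adjusted p = 0.16).

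Of the 18 KLF2/KLF4-associated flow genes, 8 were higher in PS early and 0 lower (12 and 0 adjusted over the list alone, camera adjusted p = 4.8e-28, adjusted p = 0.000404 with an estimated correlation). Of 21 NF-kB and leukocyte adhesion genes 7 were lower and 0 higher (8 and 0 adjusted over the list alone, camera adjusted p = 9.8e-07, adjusted p = 0.285 with an estimated correlation). Among them was the inhibitor gene NFKBIA (-0.31 ± 0.07). Of 19 cholesterol synthesis and uptake genes 5 were lower and 0 higher (6 and 0 adjusted over the list alone, camera adjusted p = 0.000201, adjusted p = 0.267 with an estimated correlation). IDI1 (-0.33 ± 0.07) and FDFT1 (-0.23 ± 0.06) were among them. Of 18 interferon response genes 5 were lower and 0 higher (8 and 0 adjusted over the list alone, camera adjusted p = 2.5e-06, adjusted p = 0.285 with an estimated correlation). OAS1 stood at -0.67 ± 0.15 and DDX58 at -0.27 ± 0.06, and OAS2 was chosen after its value was seen. Of 18 hypoxia and glycolysis genes 7 were lower, such as P4HA1 (-0.37 ± 0.06) and BNIP3 (-0.61 ± 0.11), and 2 higher (7 and 2 adjusted over the list alone, camera adjusted p = 4.1e-05, adjusted p = 0.267 with an estimated correlation).

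Of 20 unfolded protein and amino acid stress genes 4 were higher early and 0 lower (6 and 0 adjusted over the list alone, camera adjusted p = 0.00247, adjusted p = 0.267 with an estimated correlation). CHAC1 stood at 1.47 ± 0.31 and SESN2 at 0.49 ± 0.09. Of 12 heat shock genes 3 were higher, HSPA1A (0.54 ± 0.08), HSPA1B (0.53 ± 0.09) and DNAJB1 (0.31 ± 0.06), and 0 lower (3 and 0 adjusted over the list alone, camera adjusted p = 0.00696, adjusted p = 0.429 with an estimated correlation). In all, 499 genes were higher in PS early and 377 lower, and 64 and 26 of these differed at least 2-fold. The sign was the same in both sets for all 876. With the replicate block 1701 were called, 911 higher and 790 lower. Set A alone called 406 genes (202 higher and 204 lower) and set B alone 367 (217 and 150), the mean of 1 to 3 h called 361, and the count was 560 without the PS 4 h library of set A.

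Late differences were asked with the mean of 12 to 24 h. CD34 was higher in PS by 3.92 ± 0.28 (SE, n = 8 libraries per flow, adjusted p = 4.0e-11), by 4.21 in set A and 3.65 in set B. ITGB4 (3.56 ± 0.15), CNR1 (3.36 ± 0.17), CYP1B1 (3.15 ± 0.30) and NPR1 (3.10 ± 0.29) were higher too. ANGPT2 (-2.69 ± 0.17), CXCR4 (-2.67 ± 0.19), NOG (-1.75 ± 0.28), F3 (-1.70 ± 0.24) and TNFSF15 (-1.47 ± 0.16) were lower. KLF2 (2.38 ± 0.20), KLF4 (2.80 ± 0.14), NOS3 (1.89 ± 0.11), THBD (1.68 ± 0.17) and HMGCS1 (0.33 ± 0.07) were higher and EDN1 lower (-0.52 ± 0.06). VCAM1 (-0.21, adjusted p = 0.71) and HMOX1 (0.26, adjusted p = 0.11) did not pass. The call of HMGCS1 was lost in set A alone. ICAM1 (0.47 ± 0.16, adjusted p = 0.030) and CCL2 (-0.49 ± 0.19, adjusted p = 0.044) passed by little. ICAM1 lost its call without the OS set B library of 12, 16, 20 or 24 h or the PS set A library of 12, 16 or 20 h, with adjusted p from 0.065 to 0.096. CCL2 lost its call without the 20 h time point and without any 1 of these libraries, with adjusted p from 0.051 to 0.16: OS set A of 12, 16, 20 and 24 h, OS set B of 16 h, PS set A of 12, 16 and 24 h, and PS set B of 12, 16, 20 and 24 h.

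Of the 18 KLF2/KLF4-associated flow genes 17 were higher late and 0 lower (17 and 0 adjusted over the list alone, camera adjusted p = 1.1e-45, adjusted p = 1.5e-05 with an estimated correlation). They included the prostaglandin D synthase PTGDS (4.95 ± 0.26), the water channel AQP1 (3.95 ± 0.50), DHH (3.48 ± 0.19) and the angiopoietin receptor TEK (1.54 ± 0.08). Of 19 cholesterol synthesis and uptake genes 13 were higher and 0 lower (14 and 0 adjusted over the list alone, camera adjusted p = 8.0e-05, adjusted p = 0.233 with an estimated correlation). They included INSIG1 (0.64 ± 0.10), SC4MOL (0.50 ± 0.06) and CYP51A1 (0.40 ± 0.05). Of 16 pan-endothelial identity genes 10 were higher and 0 lower (11 and 1 adjusted over the list alone, camera adjusted p = 6.0e-07, adjusted p = 0.207 with an estimated correlation). Among these were SOX18 (2.03 ± 0.28), PECAM1 (1.06 ± 0.13), the VEGF receptor KDR (0.86 ± 0.10) and ESAM (0.48 ± 0.05). Of 16 vasoactive genes 9 were higher and 2 lower, ADM (-1.19 ± 0.11) and EDN1 (10 and 2 adjusted over the list alone, camera adjusted p = 0.00155, adjusted p = 0.482 with an estimated correlation). Of 14 flow sensor genes 7 were higher, such as PLXND1 (0.71 ± 0.08) and S1PR1 (0.48 ± 0.06), and 2 lower, FLT4 (-0.42 ± 0.10) and P2RX4 (-0.46 ± 0.13), the last chosen after its value was seen (8 and 2 adjusted over the list alone, camera adjusted p = 0.000669, adjusted p = 0.465 with an estimated correlation).

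Of 14 mesenchymal and contractile genes 7 were lower late, such as CDH2 (-0.82 ± 0.07), TPM1 (-0.81 ± 0.07) and CALD1 (-0.54 ± 0.07), and 1 higher, FSTL1 with 0.43 ± 0.04 (7 and 1 adjusted over the list alone, camera adjusted p = 0.00496, adjusted p = 0.233 with an estimated correlation). Of 20 genes of DNA replication and G1/S 7 were lower and 0 higher (9 and 0 adjusted over the list alone, camera adjusted p = 0.0138, adjusted p = 0.874 with an estimated correlation). PCNA stood at -0.49 ± 0.13, a call lost in set A alone. Of 20 G2/M cell cycle genes 5 were lower and 0 higher (5 and 0 adjusted over the list alone, camera adjusted p = 0.0329, adjusted p = 0.874 with an estimated correlation). They were CDK1, AURKB, BIRC5, AURKA and BUB1, the last chosen after its value was seen and not tested with libraries left out. AURKA lost its call (adjusted p 0.0558 to 0.171) without any of 9 of the 16 libraries, OS set A of 12 h and OS set B or PS set A of 12, 16, 20 or 24 h. BIRC5 lost its call (adjusted p 0.0579 to 0.212) without any of these but OS set A of 12 h. AURKB lost its call without OS set B of 16 h (adjusted p = 0.0604) or 20 h (0.138), and CDK1 without OS set B of 20 h (0.0683). In set A alone CDK1, AURKB and BIRC5 were not called. In the list of 21 NF-kB and leukocyte adhesion genes 4 were higher and 2 lower (4 and 2 adjusted over the list alone, adjusted p = 0.993), and its mean and median were below 0 where the test pointed up. Among the markers of other cell types, the smallest adjusted p of a list was 0.191, in 3 epithelial markers of which KRT19 was higher (1.41 ± 0.21). In all, 2280 genes were higher in PS late and 2591 lower, and 356 and 121 of these differed at least 2-fold. The sign was the same in both sets for 4869 of the 4871. In each set alone the balance turned, with 1760 higher and 1301 lower in set A (3061 in all) and 1016 and 553 in set B (1569). It turned with the stricter filter too (1998 and 1977), and without OS set A of 12 h (2216 and 1996), PS set A of 20 h (2303 and 2209) or 24 h (2131 and 1978) or PS set B of 24 h (2198 and 2075).

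**Figure D4:**
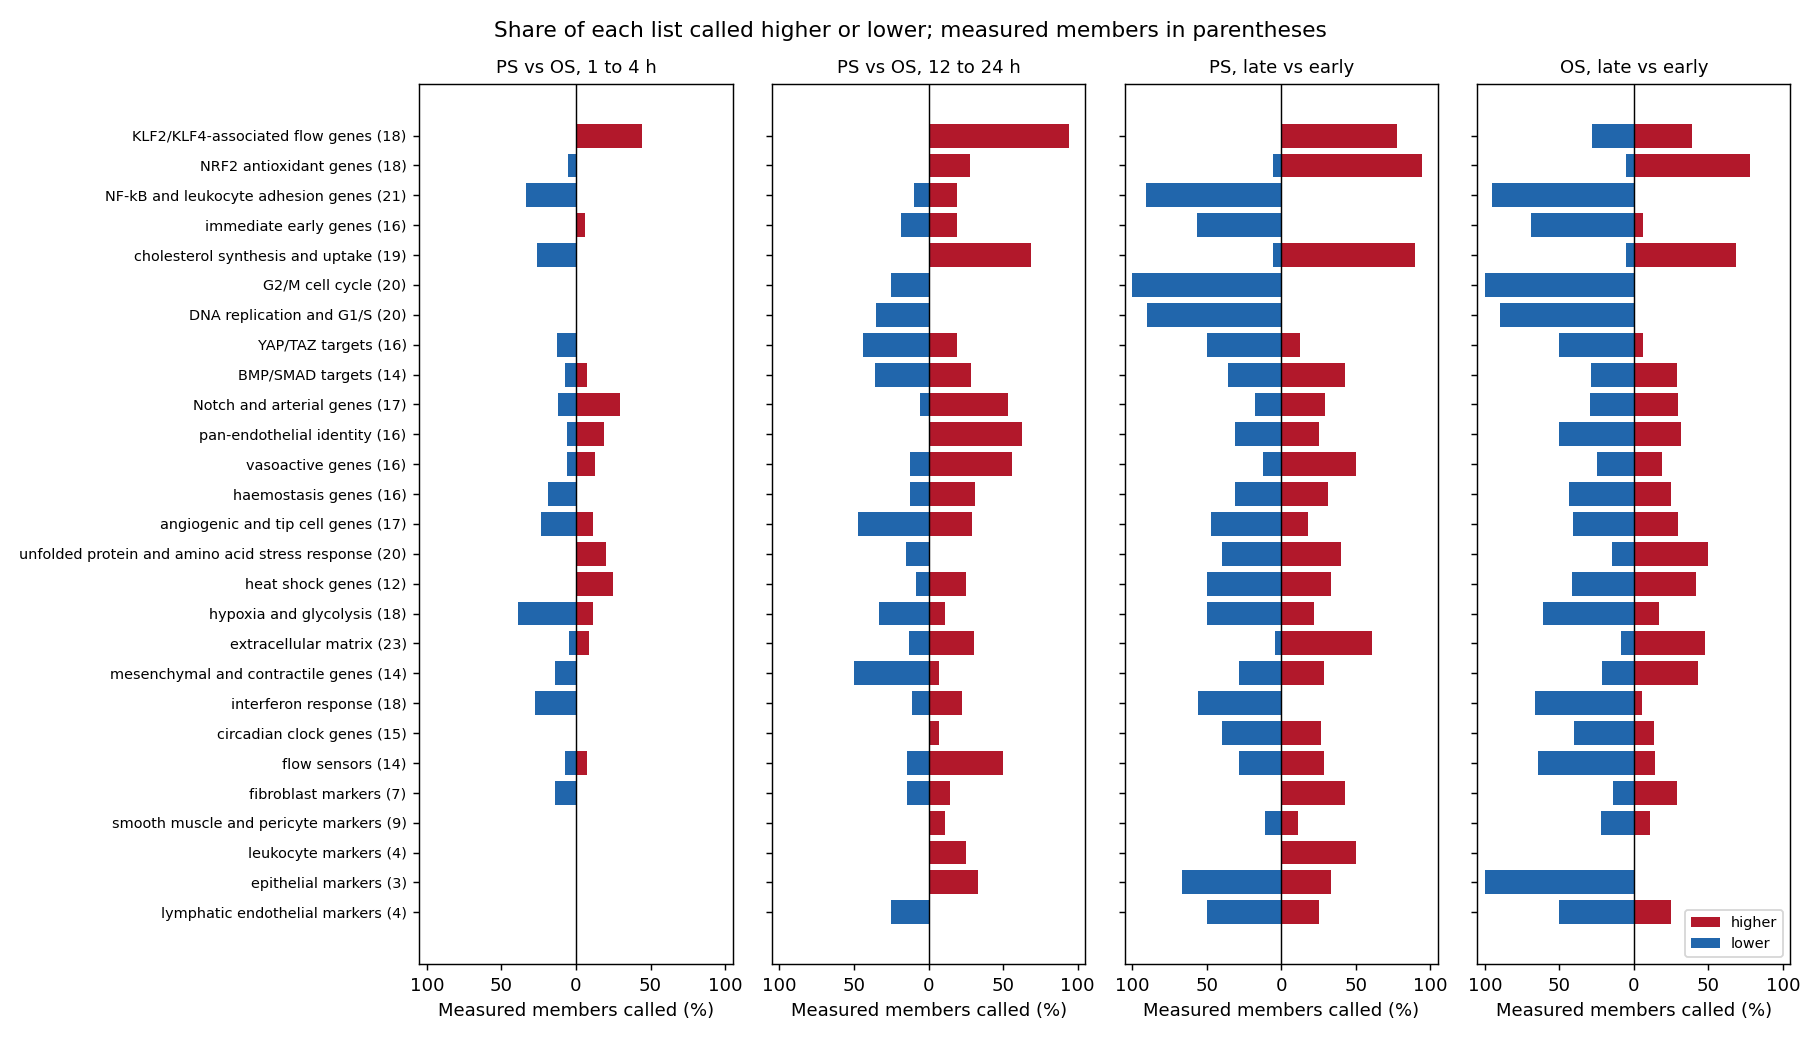
Percent of the measured members of each gene list called higher or lower, for PS against OS early and late and for late against early in PS and in OS. Of the 18 KLF2/KLF4-associated flow genes, 8 were higher in PS early and 17 late.

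Whether the flow difference itself changed with time was asked with the late minus the early difference, an interaction test. Under the naming rule CD34 had the largest increase of the PS minus OS difference, 4.79 ± 0.37 (SE, n = 8 libraries per flow and window, adjusted p = 6.0e-09). It was followed by PCDH12, a protocadherin of endothelium (2.63 ± 0.28), FAM107A (2.63 ± 0.23), ITGB4 (2.59 ± 0.19) and APOL3 (2.05 ± 0.23). The PS minus OS difference moved downward for CHAC1 (-2.06 ± 0.46), ANGPT2 (-2.05 ± 0.22), AMPH (-1.53 ± 0.22), GDF15 (-1.38 ± 0.20) and STC2 (-1.36 ± 0.24). For ANGPT2, which was lower in PS both early and late, the difference thereby widened. The difference grew for THBD (1.25 ± 0.23) and NOS3 (0.94 ± 0.15). For HMGCS1 it moved upward (0.69 ± 0.10), from lower in PS early to higher in PS late. The change of the difference in KLF4 (0.42 ± 0.19, adjusted p = 0.19) and EDN1 (0.06, adjusted p = 0.72) did not pass. The KLF2 difference was smaller late (-1.14 ± 0.28, adjusted p = 0.010), a call lost in set A alone (-0.72, adjusted p = 0.39), in set B alone (-1.27, adjusted p = 0.11) and with 1 to 3 h and 16 to 24 h (-0.89, adjusted p = 0.10). The call of CHAC1 was lost in set B alone (-1.61, adjusted p = 0.056).

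Of the 18 KLF2/KLF4-associated flow genes the difference moved upward for 10 and downward for 1, KLF2 (14 and 1 adjusted over the list alone, camera adjusted p = 9.5e-22, adjusted p = 0.00145 with an estimated correlation). Of 19 cholesterol synthesis and uptake genes it moved upward for 10 and downward for 0 (13 and 0 adjusted over the list alone, camera adjusted p = 3.4e-14, adjusted p = 0.00535 with an estimated correlation). Of 16 pan-endothelial identity genes it moved upward for 6 and downward for 0 (9 and 0 adjusted over the list alone, camera adjusted p = 8.5e-08, adjusted p = 0.101 with an estimated correlation). Of 18 interferon response genes it moved upward for 4, OAS1, OAS2, IFIH1 and OAS3, and downward for 0 (6 and 0 adjusted over the list alone, camera adjusted p = 0.000431, adjusted p = 0.468 with an estimated correlation). Of 20 unfolded protein and amino acid stress genes it moved downward for 5 and upward for 0 (5 and 0 adjusted over the list alone, camera adjusted p = 0.00239, adjusted p = 0.146 with an estimated correlation). SESN2 stood at -0.69 ± 0.13, and DDIT3 was the 1 of the 5 chosen after its value was seen. For 5 of 21 NF-kB and leukocyte adhesion genes the difference moved upward and for 0 downward (camera adjusted p = 0.00239). Adjusted over the list alone these were 6 and 0. The flow sensor, vasoactive, haemostasis, NRF2 antioxidant and hypoxia lists moved upward (camera adjusted p 0.00084 to 0.0153). The G2/M, DNA replication and mesenchymal lists moved downward (camera adjusted p 0.00084 to 0.0423). With an estimated correlation these lists had an adjusted p from 0.119 to 0.675. In all, the difference moved upward for 673 genes and downward for 450. The sign was the same in both sets for all 1123. With the replicate block the balance turned, to 1187 upward and 1293 downward. Set A alone called 930 and set B alone 453, and without the OS 20 h library of set A the count was 1948.

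What each flow did within 1 h was asked against the low flow. KLF2 was higher in PS than in ST by 2.17 ± 0.40 (SE, n = 2 libraries per group, adjusted p = 0.023), the developmental gene HEY2 by 1.21 ± 0.18, NPTX1 by 1.40 ± 0.20 and IL21R by 1.43 ± 0.26. CXCR4 (-2.04 ± 0.37) and the kinase PIM1 (-1.33 ± 0.20) were lower, and KLF4 did not pass (1.21 ± 0.26, adjusted p = 0.098). These 6 and CYP27C1 (1.72 ± 0.32, chosen after its value was seen) made up the 7 calls, 5 higher and 2 lower. The replicate block gave 26 higher and 20 lower, and DESeq2 19 and 20. With a library left out there was 1 call without ST set A, 2 without PS set A, 26 without ST set B and 2 without PS set B, and there was none in a fit of the 6 libraries of 1 h alone. The call of KLF2 was lost without any of the 4 libraries (adjusted p 0.11 to 0.18), and all 6 were lost without ST set A. Of the 18 KLF2/KLF4-associated flow genes 1 was higher in PS (3 adjusted over the list alone, camera adjusted p = 0.000448, adjusted p = 0.442 with an estimated correlation). Of 16 immediate early genes 0 passed over all genes and 3 were lower adjusted over the list alone (camera adjusted p = 2.1e-06, adjusted p = 0.442 with an estimated correlation). FOS stood at -2.25 ± 0.64 and FOSB at -2.90 ± 0.92. The NF-kB and leukocyte adhesion list had a mean of 0.39 and a median of 0.07 (0 of 21 genes passed over all genes and 0 adjusted over the list alone, camera adjusted p = 0.0179 toward higher, adjusted p = 0.810 with an estimated correlation). Its member VCAM1 stood at 34.7 CPM in PS of set A and 7.02 CPM in PS of set B, against 8.77 and 6.86 CPM in ST. Lists that lay lower in PS were interferon response (camera adjusted p = 0.000536), hypoxia and glycolysis (0.00126), YAP/TAZ targets (0.00467) and pan-endothelial identity (0.0180). Notch and arterial genes lay higher (camera adjusted p = 0.0179). With an estimated correlation the adjusted p of these lists ran from 0.442 to 0.601.

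Between OS and ST at 1 h, edgeR called 0 genes, with 457 at an unadjusted p below 0.05, and DESeq2 called 0, with 423 at an unadjusted p below 0.05. KLF2 had a difference of -0.30 ± 0.39, VCAM1 2.28 ± 0.73 and SELE 2.53 ± 0.86 (SE, n = 2 libraries per group, all with an adjusted p of 1). The differences of VCAM1 and SELE rested on the OS library of set A. VCAM1 stood at 70.1 CPM there and 6.44 CPM in OS of set B, against 8.77 and 6.86 CPM in ST of sets A and B. SELE stood at 326 and 29.5 CPM in OS of sets A and B. Without the OS 1 h library of set B 15 genes were called. The NF-kB and leukocyte adhesion list lay higher in OS than in ST (0 of 21 genes passed over all genes and 0 adjusted over the list alone, camera adjusted p = 2.9e-10, adjusted p = 0.736 with an estimated correlation). The NRF2 antioxidant list lay higher too (camera adjusted p = 0.0300). Pan-endothelial identity (camera adjusted p = 0.00974), which also lay lower in PS than in ST, and G2/M cell cycle (camera adjusted p = 0.0252) lay lower. For each of these lists the adjusted p was 0.963 with an estimated correlation.

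How the cells changed during pulsatile flow was asked with PS late against early. The series has no ST library later than 1 h, so that changes with time under flow and changes with time in the experiment were not separated. CRYAB, a small heat shock protein, was higher late by 3.92 ± 0.28 (SE, n = 8 libraries per window), MYOM3 by 2.81 ± 0.14, CYP1B1 by 2.77 ± 0.29, CLIC3 by 2.54 ± 0.16 and TMEM37 by 2.54 ± 0.15. SELE (-5.48 ± 0.49), the NF-kB target BIRC3 (-4.53 ± 0.27), ADAMTS18 (-4.18 ± 0.12), the apelin gene APLN (-3.97 ± 0.26) and NPTX1 (-3.94 ± 0.11) were lower. CCL2 (-3.79 ± 0.20), ANGPT2 (-3.37 ± 0.17), VCAM1 (-2.98 ± 0.38) and ICAM1 (-1.45 ± 0.17) were lower late and NOS3 (1.78 ± 0.11), HMGCS1 (0.96 ± 0.07) and THBD (0.90 ± 0.16) higher. Window means do not show the course between them. The mean level of ICAM1 in PS was 95.3 CPM at 1 h, 361 at 3 h, 395 at 6 h and 94.9 at 24 h. CCL2 and VCAM1 were highest at 3 h and ANGPT2 at 1 h, and each was lower at 24 h than at 1 h. KLF2 did not pass (0.14, adjusted p = 0.56). HMOX1, a haem-degrading enzyme, was higher by 0.47 ± 0.13, and its difference was -0.05 in set B alone (adjusted p = 0.94). Its highest mean level in PS was 640 CPM at 6 h, a time in neither window.

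In PS, 19 of 21 NF-kB and leukocyte adhesion genes were lower late and 0 higher (19 and 0 adjusted over the list alone, camera adjusted p = 9.7e-18, adjusted p = 0.0408 with an estimated correlation). TNFAIP3 stood at -2.32 ± 0.15. Of 20 G2/M cell cycle genes 20 were lower (20 adjusted over the list alone, camera adjusted p = 2.1e-16, adjusted p = 0.224 with an estimated correlation), such as NUSAP1 (-1.50 ± 0.12). Of 20 genes of DNA replication and G1/S 18 were lower and 0 higher (19 and 0 adjusted over the list alone, camera adjusted p = 6.7e-10, adjusted p = 0.32 with an estimated correlation), such as RRM2 (-1.71 ± 0.14). Of 18 NRF2 antioxidant genes 17 were higher and 1 lower, PIR, chosen after its value was seen (17 and 1 adjusted over the list alone, camera adjusted p = 2.6e-14, adjusted p = 0.0132 with an estimated correlation). They included OSGIN1 (2.16 ± 0.10), NQO1 (1.65 ± 0.09) and TXNRD1 (1.12 ± 0.08). Of 19 cholesterol synthesis and uptake genes 17 were higher and 1 lower (17 and 1 adjusted over the list alone, camera adjusted p = 1.1e-13, adjusted p = 0.0132 with an estimated correlation). SC4MOL (1.18 ± 0.06) was among the 17. Of the 18 KLF2/KLF4-associated flow genes 14 were higher and 0 lower (14 and 0 adjusted over the list alone, camera adjusted p = 1.4e-08, adjusted p = 0.0408 with an estimated correlation). PTGDS rose by 5.66 ± 0.28. Of 18 interferon response genes 10 were lower and 0 higher (10 and 0 adjusted over the list alone, camera adjusted p = 0.00315, adjusted p = 0.524 with an estimated correlation). In all, 3478 genes were higher late and 4035 lower, with 5289 called in set A alone and 6077 in set B alone. This balance turned with GC and length correction, chosen after seeing the data (4609 higher and 3757 lower), without a count filter (3746 and 3616) and with the stricter filter (3013 and 2927), and RLE scaling gave 3734 and 3776. Without any 1 of 8 of the 16 libraries, PS set A of 1, 2, 20 or 24 h and PS set B of 1, 2, 3 or 24 h, it turned as well. The counts ran from 3571 and 3500 without PS set A of 20 h to 3722 and 3500 without PS set A of 2 h, the smallest and largest excess of the 8. Of 4 lymphatic endothelial markers 2 were lower, FLT4 (-1.82 ± 0.10) and LYVE1 (-3.03 ± 0.24), and 1 higher, RELN with 1.11 ± 0.17 (2 and 1 adjusted over the list alone, camera adjusted p = 0.0280, adjusted p = 0.230 with an estimated correlation). Of 3 epithelial markers 2 were lower, KRT18 (-2.01 ± 0.12) and KRT8 (-0.42 ± 0.09), and 1 higher, KRT19 with 0.67 ± 0.20 (2 and 1 adjusted over the list alone, adjusted p = 0.0625).

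The same question was asked of oscillatory flow with OS late against early, with the same limit. CRYAB was higher late by 2.74 ± 0.29 (SE, n = 8 libraries per window), the growth factor gene IGF2 by 2.61 ± 0.12, TMEM37 by 2.53 ± 0.15, the arterial connexin gene GJA5 by 2.52 ± 0.22 and CCDC68 by 2.52 ± 0.17. APLN (-5.50 ± 0.28), SELE (-5.28 ± 0.49), ADAMTS18 (-4.91 ± 0.13), BIRC3 (-4.82 ± 0.27) and CCL2 (-4.22 ± 0.20) were lower. VCAM1 (-3.36 ± 0.38), ICAM1 (-1.93 ± 0.17) and ANGPT2 (-1.32 ± 0.14) were lower and NOS3 higher (0.84 ± 0.10), and THBD did not pass (-0.34, adjusted p = 0.09). KLF2 was higher by 1.28 ± 0.21, a call lost in set A alone (0.77, adjusted p = 0.21). Its mean level in OS was 17.8 CPM at 1 h, 4.25 at 3 h and 19.7 at 24 h, so that the early mean held a dip.

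In OS, 20 of 21 NF-kB and leukocyte adhesion genes were lower late (20 adjusted over the list alone, camera adjusted p = 5.0e-25, adjusted p = 0.0349 with an estimated correlation), with TNFAIP3 at -3.06 ± 0.16. Of 18 NRF2 antioxidant genes 14 were higher and 1 lower, PIR, chosen after its value was seen (14 and 1 adjusted over the list alone, camera adjusted p = 4.8e-09, adjusted p = 0.0902 with an estimated correlation). OSGIN1 rose by 2.41 ± 0.10. Of 20 G2/M cell cycle genes 20 were lower (camera adjusted p = 2.8e-09, adjusted p = 0.427 with an estimated correlation), such as KIF20A (-1.36 ± 0.14). Of 20 genes of DNA replication and G1/S 18 were lower and 0 higher (18 and 0 adjusted over the list alone, camera adjusted p = 2.1e-05, adjusted p = 0.498 with an estimated correlation). Of 19 cholesterol synthesis and uptake genes 13 were higher and 1 lower (13 and 2 adjusted over the list alone, camera adjusted p = 0.0115, adjusted p = 0.427 with an estimated correlation). Of 18 interferon response genes 12 were lower and 1 higher, IFI44, chosen after its value was seen (12 and 1 adjusted over the list alone, camera adjusted p = 2.8e-07, adjusted p = 0.427 with an estimated correlation). OAS1 stood at -3.10 ± 0.17. Of the 18 KLF2/KLF4-associated flow genes 7 were higher and 5 lower, DHH (-2.25 ± 0.19), ITPR3, AQP1 (-3.93 ± 0.50), PPAP2B and ASS1, with PPAP2B chosen after its value was seen (7 and 5 adjusted over the list alone, adjusted p = 0.903). The median of that list was above 0, its mean below 0 and its test pointed up. In all, 3549 genes were higher late and 3942 lower, with 4971 called in set A alone and 3410 in set B alone. The balance turned with GC and length correction, chosen after seeing the data (4586 higher and 3657 lower), without a count filter (3777 and 3590) and with the stricter filter (3047 and 2930), and without OS set A of 2 h (3581 and 3577) or 12 h (3521 and 3494). Of 3 epithelial markers 3 were lower late, KRT18 (-1.87 ± 0.12), KRT8 (-0.49 ± 0.09) and KRT19 (-0.56 ± 0.21), with 3 adjusted over the list alone, a camera adjusted p of 0.0141 and an adjusted p of 0.199 with an estimated correlation. KRT19 lost its call (adjusted p 0.0582 to 0.214) without the OS set A library of 12, 16, 20 or 24 h or the OS set B library of 1, 2, 3 or 4 h. Of 4 lymphatic endothelial markers 2 were lower, LYVE1 (-3.75 ± 0.25) and FLT4 (-1.20 ± 0.10), and 1 higher, RELN with 1.57 ± 0.18 (2 and 1 adjusted over the list alone, adjusted p = 0.0862).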

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

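The ratio of covariances and the 20 h correlation corrected for GC content and length were chosen as tests only after the results were seen, and the thinning, the fits without 20 h and the GC and length correction were not among the alternatives set before. The splits of the libraries were set before.

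The PS minus OS difference differed between late and early times, by the interaction test, for 1123 genes. The largest log2 changes of the difference under the naming rule were 4.79 for CD34, 2.63 for PCDH12, 2.63 for FAM107A, 2.59 for ITGB4 and 2.05 for APOL3. On the other side were -2.06 for CHAC1, -2.05 for ANGPT2, -1.53 for AMPH, -1.38 for GDF15 and -1.36 for STC2. As a list, the KLF2/KLF4-associated flow genes had a mean change of 1.08, and the cholesterol synthesis and uptake genes of 0.36.

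The number of genes called between PS and OS was 10 at 1 h and 1226 at 24 h. A smaller spread between late libraries is argued against by the covariance across genes of the set A and set B differences, to which independent noise adds nothing: it was 6.74 times as large at 24 h as at 1 h (95% bootstrap interval over genes, which are not independent, 5.78 to 7.95). That interval does not measure the spread between libraries. The spread between the sets across genes was 0.138 at 1 h and 0.164 at 24 h on the log2 scale, and so not smaller late. Unequal depth is argued against by 1125 calls at 24 h and 8 at 1 h with every library thinned to 23.6 M counts. A trend with GC content and length is argued against as the whole cause by 1571 calls at 24 h and 17 at 1 h after its removal. The hypothesis that stays is that the flows may part further with time under flow, found and tested on the same libraries.

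At 20 h the differences between PS and OS in set A and in set B went less together than at the other late times, with a correlation across genes of 0.22 against 0.77, 0.86 and 0.70 at 12, 16 and 24 h. Depth of a single library is argued against by a correlation of 0.217 with every library thinned to the lowest total. After removal of the GC content and length trend the correlation was 0.517, between 0.35, below which the trend was to be set aside, and 0.697 at 24 h, so that the trend as the cause cannot be told apart from others. The set difference of the OS 20 h libraries had a Spearman correlation with length of -0.64, outside the range of the other 20 groups (-0.39 to 0.60), and the trend held 40.6% of its variance against 2.38 to 47.3% in the others. The OS 20 h library of set B had the highest total of all libraries, 52.7 M counts. Its share of ribosomal protein counts was also the highest, 7.03% against 4.77% in the OS 20 h library of set A. Whether this library alone was the source was not tested. No biological explanation was tested.

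The PS minus OS list mean of the cholesterol synthesis and uptake genes was -0.08 at 1 h, -0.20 at 3 h and 0.31 at 24 h, and with an estimated correlation the late minus early test held (adjusted p = 0.00535) while the early (0.267) and late (0.233) tests did not. The 20 h libraries are argued against as the cause by a mean late minus early change of 0.354 without them (camera p = 0.00044 with an estimated correlation, limma). A GC content and length trend is argued against by 0.374 after its removal (limma camera p = 0.0014 with an estimated correlation). The change was 0.29 in set A, with 18 of 19 genes upward, and 0.44 in set B, with 19 of 19. That flow itself may turn this list with time is a hypothesis, found and tested on the same libraries.

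Whether other groupings of the libraries call as many genes was counted over 100 splits per comparison. In each of the 6 comparisons 1 split, the real one, called as many. The smallest share that 100 splits can show is 1 in 100. Splits that mix the compared sides put their real difference into the spread, and the median count of the other splits was 0. The counts of the splits therefore do not exclude chance by themselves. For PS against OS over 10 times the real count was 4992 and the highest other 101. Early they were 876 and 176, late 4871 and 3843, and for late minus early 1123 and 214. The late split with 3843 calls had 14 of the 16 libraries on their real side. For late against early they were 7513 and 1563 in PS, and 7491 and 3478 in OS.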

How the results depend on the processing

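The fits without the 20 h time point, for late minus early within each set and with GC and length correction were chosen after seeing the data. With RLE scaling and with the stricter filter all 18 counts of genes stayed within 1.5 times, as did all 5 without the 20 h time point. The values below lie beyond that or reversed, and the cause was not tested unless given. With 2 libraries per group, the fit recovered 26% of 1.5-fold changes at 24 h and 20% for PS against ST in simulated data without set differences. With every library thinned to 23.6 M counts, 1125 genes were called at 24 h against 1226.

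The replicate block, the set as a term, rests on a check of the libraries: 186 of 210 correlations of set differences between groups exceeded 0.1 (median 0.19, from -0.20 to 0.45), and the term itself called 2850 genes higher and 3258 lower in set B. With it there were 1701 calls early, 2480 for late minus early, 37 at 1 h, 90 at 2 h, 157 at 3 h, 536 at 4 h, 538 at 6 h, 963 at 9 h, 1057 at 12 h, 1143 at 16 h, 2041 at 20 h, 2480 at 24 h and 46 for PS against ST, and all calls made without the term were among them. Without a count filter (19350 genes) there were 49 at 3 h and 13 for PS against ST. DESeq2 called 31 at 1 h, 57 at 2 h, 103 at 3 h, 361 at 4 h and 39 for PS against ST. The compared groups alone, with fewer libraries for the spread, gave 0 at 1 h, 5 at 2 h, 4 at 3 h, 0 at 4 h, 22 at 6 h, 1065 at 16 h, 103 at 20 h and 0 for PS against ST. Set A alone, with fewer libraries, gave 406 early, 3061 late and 4971 for OS late against early. Set B alone gave 2843 over 10 times, 367 early, 1569 late, 453 for late minus early and 3410 for OS late against early, and HMOX1 reversed there for PS late against early (-0.049, adjusted p = 0.94). The narrow windows gave 361 early. GC and length correction gave 1689 for late minus early, 17 at 1 h, 63 at 2 h, 78 at 3 h, 422 at 6 h, 614 at 9 h, 631 at 12 h, 910 at 16 h and 23 for PS against ST. Of the 69 list tests called with the preset correlation, 10 were called with an estimated one.

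Each library was left out in turn, and a group's lone library was then assumed to vary like the other groups. Of the 184 counts, 143 stayed within 1.5 times and 41 moved. The ranges were 4366 to 5816 over 10 times, 560 (without PS 4 h A) to 1023 early, 3848 to 5920 late, 867 to 1948 (without OS 20 h A) for late minus early, 6902 to 7306 for PS late against early and 6977 to 7767 for OS late against early. In the order OS A, PS A, OS B and PS B the counts were 2, 1, 29 and 4 at 1 h, 10, 3, 5 and 9 at 2 h, 149, 142, 106 and 198 at 9 h, 134, 112, 117 and 253 at 12 h, and 213, 199, 161 and 270 at 16 h. At 3 h they were 4 without OS A, 4 without PS A, 15 without PS B and up to 24 without OS B. At 4 h they were 28 without OS A, 15 without PS A, 48 without OS B and up to 213 without PS B. At 6 h they were 76 without OS A, 61 without PS A and up to 240 without PS B. At 20 h they were 3303 without OS A, 334 without OS B and 382 without PS B, and at 24 h 406 without OS A, 495 without PS A, 581 without PS B and up to 825 without OS B. For PS against ST they were 1 without ST A, 2 without PS A, 26 without ST B and 2 without PS B, and for OS against ST 0 to 15, the last without OS B.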

Other observations

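Several lists of genes fixed beforehand held members that moved both ways between PS and OS over the 10 times without a call of the list. Of 16 immediate early genes 4 were higher in PS, NR4A1 (0.71 ± 0.11), JUNB (0.60 ± 0.10), DUSP1 (0.39 ± 0.07) and IER2 (0.20 ± 0.07), and 3 lower, ATF3 (-0.63 ± 0.13), EGR1 (-0.67 ± 0.15) and IER3 (-0.34 ± 0.07), with an adjusted p of the list of 0.906 (4 and 3 adjusted over the list alone). IER2, IER3 and EGR1 were chosen after their values were seen. Of 14 BMP/SMAD targets 5 were higher, such as ID1 (0.67 ± 0.09), and 5 lower, such as NOG and BMP4 (-0.52 ± 0.08), with a list median of 0.10, a mean of -0.01 and an adjusted p of 0.982 (6 and 5 adjusted over the list alone). Of 16 YAP/TAZ targets 7 were lower, such as CYR61 (-0.51 ± 0.05), and 3 higher, LATS2 (0.27 ± 0.05) with PTPN14 and AXL, the last 2 chosen after their values were seen (adjusted p = 0.118, 7 and 3 adjusted over the list alone). Of 16 haemostasis genes 3 were higher, THBD, PROCR and SELP, and 2 lower, F3 and F2RL1 (adjusted p = 0.900, 3 and 2 adjusted over the list alone), with SELP chosen after its value was seen. PROCR was not called in set B alone (0.10, adjusted p = 0.165). Of 23 extracellular matrix genes 4 were higher, among them ELN (2.32 ± 0.29), and 5 lower, among them MMP10 with -0.74 ± 0.09 (adjusted p = 0.578, 4 and 5 adjusted over the list alone). Of 15 circadian clock genes 1 was higher, NPAS2, and 3 lower, NR1D2, TEF and PER2 (adjusted p = 0.906, 1 and 3 adjusted over the list alone), with a median above 0 and a mean below 0. NPAS2 was not called in set A alone (0.06, adjusted p = 0.332), without the 20 h time point (0.10, adjusted p = 0.0725) or after GC and length correction (0.08, adjusted p = 0.0715), the last 2 chosen after seeing the data. TEF (adjusted p = 0.111) and PER2 (adjusted p = 0.217) were not called in set B alone. PER2 lost its call (adjusted p 0.051 to 0.064) without the OS set B library of 1, 3, 12 or 24 h or the PS set A library of 2, 6, 20 or 24 h.

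Lists of markers of other cell types were also tested. Of 9 red cell markers 0 were measured. Of 7 fibroblast markers 1 was lower in PS over the 10 times, PDGFRA with -0.97 ± 0.15 (adjusted p of the list = 0.881), with a list median above 0 and a mean below 0. Of 9 smooth muscle and pericyte markers 1 was higher, MYH11, and 1 lower, LMOD1 (adjusted p = 0.900). MYH11 lost its call without the PS set A library of 6, 12 or 16 h (adjusted p 0.0502 to 0.0624) and after GC and length correction, chosen after seeing the data (adjusted p = 0.089). Of 4 leukocyte markers 1 was higher, CD68 with 0.29 ± 0.03 (adjusted p = 0.571), of 3 epithelial markers 2, KRT19 and KRT18 (adjusted p = 0.118), and of 4 lymphatic endothelial markers 1, PROX1 with 0.36 ± 0.10 (adjusted p = 0.900). In set A alone PROX1 (0.29, adjusted p = 0.206), LMOD1 (-0.47, adjusted p = 0.071) and MYH11 (0.58, adjusted p = 0.0523) were not called, nor in set B alone MYH11 (0.12, adjusted p = 0.586) and KRT18 (0.17, adjusted p = 0.113). KRT18 lost its call (adjusted p 0.051 to 0.064) without the OS set A library of 1, 3, 9, 16 or 20 h, OS set B of 6 h, PS set A of 4 h, or PS set B of 1, 3, 12 or 16 h.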
